A study of Homo sapiens with 6 samples.

How the data were processed

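RNA-seq of U2932 cells was analysed from 1 table of 24316 gene rows with 6 libraries, 3 with 100 µM artesunate for 24 h and 3 controls, grouped by the treatment label. The values are whole-number read counts per gene and FPKM (fragments scaled to transcript length and library size) as deposited by the authors. The submitters' processing notes name StringTie, DESeq2 1.26.0 and the genome build GRCh38. The aligner, the counter and whether strand was used in counting are not given in the sources used here, so reads of overlapping genes on either strand and of near-identical paralogs may be assigned to either. The table mixes gene symbols with 4384 StringTie loci and 8 Ensembl identifiers; 2755 rows held 0 counts in all libraries. Of the symbol rows 18993 matched a RefSeq symbol and 318 an older symbol, and 613 matched neither. Coordinates are from GENCODE 29 on GRCh38.

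Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit of group alone). A gene was called at a Benjamini-Hochberg adjusted p below 0.05. CPM values use the TMM-scaled library sizes, with factors of 1.02, 0.886 and 0.925 in artesunate replicates 1 to 3 and 1.07, 1.05 and 1.06 in the controls. Totals ran from 50129643 to 55735134 counts per library. Ratios of summed counts have intervals at 95% that cover counting error only, and a count of 0 was set to a floor of 3 counts over the group; reads are not independent molecules. No replicate pair agreed within sampling noise: chi-square per degree of freedom was 11.7 to 91.3.

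The 32 gene lists (944 entries, 894 distinct genes) were written before the data were examined, as were the tests and most alternatives; 2 entries had no row in the table. Lists were tested with camera (limma 3.58.1, voom weights, correlation preset to 0.01), with camera using an estimated correlation, and with fry, and adjusted over the 32 lists. With 6 libraries the estimated form has few degrees of freedom and so less power. A list that it did not call is not thereby shown to be unchanged. The genes named are the 12 called genes with the largest rise and the 12 with the largest fall (a symbol, a mean CPM of at least 5 and no overlap between groups), up to 4 called members of each list with the largest absolute log2 fold change, and 16 anchor genes whatever their result, 138 genes in all; a few of these are not reported here. Genes outside that rule are named only where the text says that they were chosen after their values were seen.

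The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper quartile factors, library size alone, no filter, a CPM of at least 1 in 3 libraries, a replicate block, the FPKM values on the log2(FPKM + 1) and log2(FPKM + 0.1) scales with limma (mean FPKM of at least 0.5, or no filter), mitochondrial genes left out, no robust estimation, glmTreat against 2-fold, and each library left out. Leaving out the StringTie loci and Ensembl rows, and RLE factors for the lists, were added after seeing the data. Fold changes on the log2(FPKM + 1) scale understate the change of low genes. The camera test already uses voom, so limma-voom gives no separate value for the lists.

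The tests were tested on simulated counts with 200 changed genes for artesunate against control. On 16384 genes edgeR recovered 37.3% of 1.5-fold, 65.7% of 2-fold and 83.3% of 4-fold changes, and 13 of its 137 calls (9.49%) were false, above the 5% aimed at. False calls were 7.69% for limma-voom, 23.0% for DESeq2 and 3.64% for limma on FPKM. Camera, its estimated form and fry each called both planted lists, and the preset form called 1 of 30 others. Simulated genes were drawn independently, whereas the estimated correlation within a list reached 0.908 in the data. Some of the 30 others also share members with the planted lists, so not all were unchanged. The simulation therefore cannot give the rate of false or missed list calls in the data. In the data 8570 genes passed, so the adjustment is less strict there than in the simulation. The shares of recovered genes and of false calls therefore do not carry over to the data.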

Results

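RNA was sequenced from U2932 cells, a human line of diffuse large B-cell lymphoma, in 3 libraries after 24 h with 100 µM artesunate and in 3 control libraries. Artesunate is an artemisinin derivative used against malaria, and its peroxide bridge reacts with iron and haem. The labels describe the control both as no treatment and, in the protocol, as DMSO, so it is called control here. The deposited counts summed to 50129643, 54649749 and 52696641 in artesunate replicates 1 to 3 and to 55735134, 55410008 and 51644122 in control replicates 1 to 3. Levels are mean CPM, counts scaled to a common library size, with their SD (n = 3), and log2 fold changes carry the SE of the edgeR model. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Genes named for moving against their list, and the overlapping genes BEST1, MAP6D1 and AC068946.2, were chosen after their values were seen.

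The submitters' stated purpose was to find genes tied to artesunate-induced death of these cells, with an emphasis on ferroptosis, a form of cell death that depends on iron and lipid peroxidation. Metallothionein, heat shock, chaperone and integrated stress response genes rose with artesunate, and DNA replication and B cell genes fell. MT2A, which encodes a metal-binding metallothionein, rose 45.6-fold from 10.5 ± 1.60 to 479 ± 5.93 CPM. The cystine transporter gene SLC7A11 rose 5.58-fold from 40.9 ± 4.77 to 228 ± 26.4 CPM. F13A1, the coagulation factor XIII A subunit gene, was 14.9-fold lower, at 11.3 ± 1.85 against 169 ± 14.4 CPM. TCL1A, a B cell gene, was 3.97-fold lower, at 84.1 ± 1.77 against 334 ± 6.34 CPM.

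Of 16926 tested genes, 8570 (50.6%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 4292 rose and 4278 fell. At least 2-fold change was seen for 2774 of them, of which 1361 rose and 1413 fell. In 60.9% of tested genes the groups did not overlap, where chance gives 10%. The even split rested on the scaling, because library size alone gave 2925 that rose and 5497 that fell and moved the median log2 fold change of all genes by -0.17. Fold changes are therefore relative to that scaling. Genes at least 2-fold changed by a test against that size (edgeR glmTreat) numbered 664.

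Among the 12 largest rises were 4 metallothionein genes. MT1X rose 33.3-fold (log2 5.06 ± 0.17) and MT1F 33.4-fold (5.06 ± 0.28). MT1H held 3 counts over the 3 control libraries, and the ratio to artesunate was 1300, with a counting interval of 445 to 6308 at 95%; its log2 fold change of 10.16 became 11.03 without control replicate 3. These genes are near-identical paralogs on chromosome 16, where GENCODE 29 (GRCh38) places MT2A at 56608199 to 56609497, so the share of each is uncertain. The other rises were the heat shock genes HSPA6 (9.07 ± 2.0), HSPA1A (5.77 ± 0.89) and HSPA1B (5.67 ± 0.91), the chemokine genes CXCL8 (7.31 ± 1.41), CCL3L3 (7.07 ± 1.34) and CCL3 (5.89 ± 1.13), the transcription factor gene FOS (6.39 ± 1.00) and AC005192.1 (7.20 ± 0.81). The 13 control counts of AC005192.1 all lay in control replicate 2, with 0 in control replicates 1 and 3, so its fold rests on that library. Without artesunate replicate 2 the log2 fold change was 7.75 for HSPA6, 4.93 for HSPA1A, 4.84 for HSPA1B, 6.69 for CXCL8 and 5.65 for FOS, and without control replicate 3 that of HSPA6 was 10.05. HSPA1A and HSPA1B, and CCL3 and CCL3L3, are also near-identical pairs whose reads can be split between copies.

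The 12 largest falls included B cell and precursor genes: VPREB3, part of the surrogate light chain family, was 5.42-fold lower (log2 -2.44 ± 0.12), RAG1, a recombinase gene, 5.45-fold (-2.45 ± 0.23), and MME, the CD10 gene, 5.65-fold (-2.50 ± 0.09). FCRL3 (-2.90 ± 0.27), an Fc receptor-like gene, CLEC17A (-2.62 ± 0.21), SLA (-2.97 ± 0.32), PLD4 (-3.52 ± 0.19), PDZRN4 (-3.23 ± 0.18), GASK1B (-2.36 ± 0.16) and ENG (-2.29 ± 0.32) fell with them. AC131160.1 had 0 counts in all artesunate libraries against 15.3 ± 1.87 CPM, which is at least 758-fold lower against a floor of 3 counts over the group. Its exons share 54.9% of their bases with MAP6D1, so its reads are uncertain.

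Ferroptosis genes moved in both directions, as did all tested genes, of which 4292 rose and 4278 fell of 16926. SLC7A11 (chromosome 4, 138164097 to 138242349) and its partner SLC3A2 (1.95 ± 0.17) rose, as did the ferritin genes FTH1 (2.04 ± 0.10) and FTL (1.72 ± 0.16) and the ubiquinone reductase gene AIFM2 (1.06 ± 0.13). GPX4, the peroxidase that removes lipid peroxides, was at 112 ± 17.3 against 103 ± 1.33 CPM (0.12 ± 0.11, 95% interval -0.12 to 0.37; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.369). ACSL4, which loads polyunsaturated fatty acids into phospholipids, was at 115 ± 7.21 against 123 ± 2.37 CPM (-0.10 ± 0.07; edgeR, Benjamini-Hochberg adjusted p = 0.285). Of 22 suppressors tested 9 rose, 6 fell and 7 did not pass, with the same counts adjusted over the list alone. Of 28 drivers tested 10 rose, 6 fell and 12 did not pass, with the same counts adjusted over the list alone. HMOX1, haem oxygenase (2.73 ± 0.47), TFRC, the transferrin receptor (1.48 ± 0.11), and CHAC1 (1.46 ± 0.18) rose, and ALOX5, arachidonate 5-lipoxygenase, was 4.14-fold lower (-2.05 ± 0.19). The camera test passed for neither list (Benjamini-Hochberg adjusted p = 0.128 and 0.378), and fry, which does not compare a list with other genes, called both up (Benjamini-Hochberg adjusted p = 0.00256 and 0.0235). GPX4 was called without artesunate replicate 1 (log2 0.25, edgeR, Benjamini-Hochberg adjusted p = 0.0294) and fell below 0 with library size alone (-0.05). ACSL4 was called with library size alone (-0.27, edgeR, Benjamini-Hochberg adjusted p = 0.0102) and in the 3 FPKM fits (-0.28 to -0.29; limma, Benjamini-Hochberg adjusted p = 0.00894 to 0.0113).

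**Figure D1:**
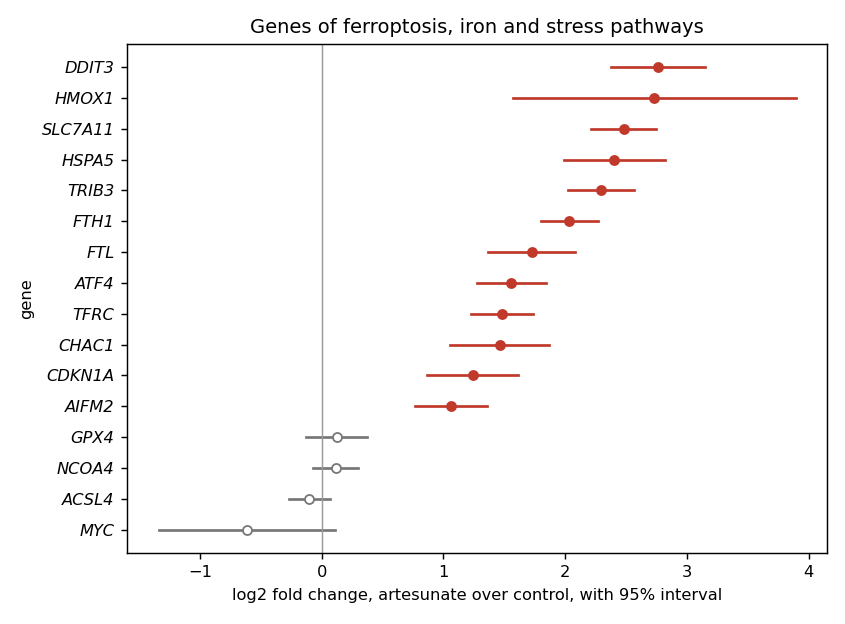
Log2 fold change of artesunate over control (x axis) with its 95% interval for 16 genes of ferroptosis, iron and stress pathways chosen before the data were examined, 3 libraries per group. Filled red points passed the test at an adjusted p below 0.05 and open grey points did not: 12 genes have their whole interval above 0, and the intervals of GPX4, NCOA4, ACSL4 and MYC include 0, while GPX4 and NCOA4 change sign with library size alone.

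Iron and haem genes also split, as all 16926 tested genes did (4292 rose and 4278 fell). HEPH, a copper-dependent ferroxidase gene (3.07 ± 0.50), rose with HMOX1, FTH1, FTL and TFRC. HEPH was tested in 17 alternatives only, since low genes drop out where a CPM of at least 1 or a mean FPKM of at least 0.5 is required. Its lowest log2 fold change was 0.21, over alternatives that include the log2(FPKM + 1) scale, which understates the change of low genes. Of 28 iron genes 10 rose, 9 fell and 9 did not pass (11 and 9 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.341). NCOA4, the receptor for ferritin turnover, was at 272 ± 19.9 against 251 ± 6.05 CPM (0.12 ± 0.08; edgeR, Benjamini-Hochberg adjusted p = 0.259), and below 0 with library size alone (-0.06). In haem synthesis ABCB6 (0.87 ± 0.10) and SLC25A38 (0.72 ± 0.11) rose, ALAD (-0.93 ± 0.12) fell, and 3 of 12 rose, 4 fell and 5 did not pass (4 and 6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.588). On the annotation, 62.4% of the exon bases of FTH1 are shared with BEST1 on the opposite strand, and BEST1 rose from 12.4 ± 9.61 to 197 ± 48.2 CPM, so without a stated strand their reads cannot be told apart. Reads are likewise uncertain for ABCB6, which shares 54.7% of its exon bases with AC068946.2 on the same strand, and for HSPA1B (36.5%, same strand), CCL3 (74.6%), BCL2L1 (43.0%), ACAT2 (33.9%), DDIT3 (27.2%) and RAD54L (25.1%), the last 5 with a gene on the opposite strand.

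Targets of NRF2, the regulator of the antioxidant response, rose: 20 of 31 rose, 4 fell and 7 did not pass (21 and 5 adjusted over the list alone). The 4 that fell were ABCC4 (-0.62), AKR1B1 (-0.50), CBR1 (-0.50) and ABCC1 (-0.30). OSGIN1 rose 23.8-fold (4.57 ± 0.25), SQSTM1, an autophagy receptor gene, 8.73-fold (3.13 ± 0.22) and TXNRD1, thioredoxin reductase, 3.34-fold (1.74 ± 0.11). The camera test passed (Benjamini-Hochberg adjusted p = 7.1e-07), with adjusted p = 0.234 with an estimated correlation. Of 29 glutathione genes 8 rose, 8 fell and 13 did not pass, the same adjusted over the list alone, with GCLM, a subunit of the rate-limiting ligase, 3.02-fold higher (1.59 ± 0.10). That list's camera direction was up while its median was -0.04 (Benjamini-Hochberg adjusted p = 0.711). Of 21 selenoprotein genes 7 rose, 2 fell and 12 did not pass, the same adjusted over the list alone; SELENOS (2.46 ± 0.15) and SELENOK (2.29 ± 0.21), of endoplasmic reticulum protein degradation, SELENOM (1.45 ± 0.31) and TXNRD1 rose. Its camera call (Benjamini-Hochberg adjusted p = 0.0436; adjusted p = 0.409 with an estimated correlation) was also lost with a CPM minimum of 1 (adjusted p = 0.0725) and under the FPKM scaling the list median was -0.05.

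The integrated stress response and the unfolded protein response of the endoplasmic reticulum rose. Of 40 genes of the ATF4 list 35 rose, 1 fell (ALDH18A1, -0.52) and 4 did not pass (37 and 1 adjusted over the list alone). ATF4 itself rose 2.94-fold from 411 ± 20.1 to 1209 ± 183 CPM, DDIT3, the CHOP transcription factor gene, 6.78-fold, PPP1R15A, a phosphatase subunit gene, 13.1-fold, GDF15, a stress cytokine gene, 31.2-fold, ATF3 11.5-fold and the pseudokinase gene TRIB3 4.90-fold. The list passed camera with a Benjamini-Hochberg adjusted p = 1.44e-14, with adjusted p = 0.234 with an estimated correlation. Of 29 endoplasmic reticulum chaperone and ATF6 or XBP1 target genes 28 rose, 0 fell and 1 did not pass, the same adjusted over the list alone. DNAJB9 rose 9.02-fold (3.17 ± 0.21), the chaperone gene HSPA5 5.29-fold from 397 ± 24.1 to 2101 ± 517 CPM, DNAJC3 4.87-fold and MANF 4.67-fold. Camera gave a Benjamini-Hochberg adjusted p = 2.35e-15, with adjusted p = 0.254 with an estimated correlation.

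Cytosolic heat shock, immediate early and interferon-stimulated genes rose, to different extents between the artesunate libraries. Of 19 heat shock genes 17 rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone), and DNAJB1 (4.35 ± 0.89) and the co-chaperone gene BAG3 (3.02 ± 0.68) rose with HSPA1A. Of 27 immediate early genes 21 rose, 2 fell and 4 did not pass, the same adjusted over the list alone, with JUN (4.67 ± 0.92), FOSL1 (3.76 ± 0.47) and DUSP1 (3.70 ± 0.89) among the rises and EGR3 (-1.52) and BTG2 (-0.47) falling. Of 35 interferon-stimulated genes 28 rose, 1 fell (GBP1, -1.02) and 6 did not pass (31 and 1 adjusted over the list alone), with RSAD2 (4.50 ± 0.90), HERC5 (4.13 ± 0.56), IFIT2 (3.89 ± 0.61) and OASL (3.70 ± 0.54) leading. RSAD2, HERC5 and FOSL1 were tested in 17 alternatives only. Low genes drop out where a CPM of at least 1 or a mean FPKM of at least 0.5 is required. The lowest log2 fold changes of RSAD2, HERC5 and FOSL1 were 0.64, 0.42 and 0.60. Those alternatives include the log2(FPKM + 1) scale, which understates the change of low genes. IFIT2 and OASL were tested in 20, with lowest values of 2.77 and 1.69. The replicate block ended the call of RSAD2 (edgeR, Benjamini-Hochberg adjusted p = 0.0515). Camera passed for the 3 lists (Benjamini-Hochberg adjusted p = 5.83e-07, 8.77e-05 and 8.74e-08), with adjusted p = 0.492, 0.50 and 0.492 with an estimated correlation. The median log2 difference of the heat shock list from the controls was 0.69 in artesunate replicate 1 against 1.54 and 1.42 in replicates 2 and 3, that of the immediate early list 0.59 against 1.97 and 1.36, and that of the interferon list 1.08 against 1.92 and 1.75. Control replicate 1 stood at 0.42 for the interferon list, against -0.19 and -0.15 in control replicates 2 and 3. Without artesunate replicate 2 the log2 fold change was 3.89 for JUN, 3.52 for DNAJB1, 2.84 for DUSP1, 2.43 for BAG3 and 3.91 for RSAD2, which was 5.72 without control replicate 1. With limma-voom 9 named genes lost their call: HSPA6, CXCL8, CCL3, CCL3L3, FOS, JUN, DUSP1, BAG3 and CD14 (limma adjusted p = 0.0526 to 0.247). Leaving out control replicate 1, 2 or 3 ended 4, 6 and 10 named calls, among them HSPA6 each time (edgeR, Benjamini-Hochberg adjusted p = 0.0541, 0.0752 and 0.0712). DUSP1 was also lost each time (0.0574, 0.0830 and 0.0696). Without control replicate 2 or 3 the calls of DNAJB1 (0.0536 and 0.0526) and BAG3 (0.0665 and 0.0574) were lost.

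Of 34 NF-kB targets 13 rose, 11 fell and 10 did not pass, the same adjusted over the list alone. The chemokine genes CXCL8 and CCL3 rose, and CCL22 (-3.16 ± 0.41) and the cytokine gene IL10 (-2.69 ± 0.36), both below 2 CPM, fell. Camera did not pass (Benjamini-Hochberg adjusted p = 0.808); the median was -0.04 and the mean 0.43.

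DNA replication genes fell. Of 42 genes of the G1/S transition and DNA replication 38 fell, 0 rose and 4 did not pass (39 and 0 adjusted over the list alone): MCM4, a subunit of the replicative helicase, was 2.96-fold lower (-1.57 ± 0.11), POLE2, of DNA polymerase epsilon, 2.76-fold (-1.47 ± 0.14), the ligase gene LIG1 2.65-fold (-1.41 ± 0.12) and MCM5 2.59-fold (-1.37 ± 0.12). The list passed camera with a Benjamini-Hochberg adjusted p = 1.43e-13, with adjusted p = 0.462 with an estimated correlation. Of 28 homologous recombination and Fanconi anaemia genes 21 fell, 0 rose and 7 did not pass, the same adjusted over the list alone, with RAD54L (-1.37 ± 0.23), BRIP1 (-1.31 ± 0.14), FANCD2 (-1.18 ± 0.08) and FANCI (-1.03 ± 0.12) falling most; camera gave a Benjamini-Hochberg adjusted p = 1.33e-06, with adjusted p = 0.409 with an estimated correlation. Of 40 mitotic genes 16 fell, 3 rose and 21 did not pass, the same adjusted over the list alone. CENPF (-1.04 ± 0.13), the proliferation marker gene MKI67 (-1.02 ± 0.14) and TOP2A (-0.89 ± 0.12) fell and UBE2S (1.14 ± 0.18) rose. In artesunate replicates 1 to 3 the median log2 difference from the controls was -1.28, -0.74 and -1.10 for the replication list, -0.69, -0.40 and -0.57 for the recombination list and -0.38, -0.18 and -0.21 for the mitotic list. For the mitotic list control replicates 1 to 3 stood at -0.19, 0.20 and 0.02, so control replicate 1 lay close to artesunate replicates 2 and 3. The mitotic list's camera call (Benjamini-Hochberg adjusted p = 0.0167; adjusted p = 0.710 with an estimated correlation) was lost without artesunate replicate 1 (adjusted p = 0.0644) and without control replicate 2 (adjusted p = 0.120).

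Among p53 targets 11 of 25 rose, 7 fell and 7 did not pass (13 and 8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.398). CDKN1A, the p21 cell cycle inhibitor gene, rose 2.36-fold (1.24 ± 0.16), and DDB2, of nucleotide excision repair, fell (-1.14 ± 0.10). In the BCL2 family 6 of 18 rose, 4 fell and 8 did not pass (7 and 6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.889). The pro-apoptotic genes BBC3 (1.57 ± 0.29) and PMAIP1 (1.48 ± 0.17) rose, and the anti-apoptotic genes BCL2L1 (-1.20 ± 0.13) and BCL2A1 (-0.92 ± 0.23) fell. The call of BCL2A1 was lost without artesunate replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0660).

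More lipid synthesis genes fell than rose. Of 24 cholesterol genes 14 fell, 0 rose and 10 did not pass, the same adjusted over the list alone, with ACAT2 (-1.40 ± 0.13), DHCR7 (-1.20 ± 0.12) and MVK (-1.06 ± 0.12) among those that fell. Of 23 fatty acid genes 9 fell, 2 rose and 12 did not pass, the same adjusted over the list alone, with a list median of -0.15. ACACB (-1.64 ± 0.13), the desaturase gene FADS2 (-1.58 ± 0.09), ELOVL2 (-1.35 ± 0.12) and ACSS2 (-1.19 ± 0.18) fell, and ME1 (1.16), an NADPH-producing enzyme gene, and ACSL3 (0.61) rose. The cholesterol list's median log2 difference from the controls was -0.72 in artesunate replicate 1 against -0.40 and -0.48 in replicates 2 and 3. Camera passed for both (Benjamini-Hochberg adjusted p = 0.000346 and 0.00514), with adjusted p = 0.492 and 0.234 with an estimated correlation.

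Of 34 hypoxia and glycolysis genes 12 rose, 8 fell and 14 did not pass, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.711). EGLN3 (2.37 ± 0.27), the glucose transporter gene SLC2A3 (1.86 ± 0.14), NDRG1 (1.76 ± 0.18) and VEGFA (1.20 ± 0.16) rose. Mitochondrially encoded genes rose: 11 of 13 rose, 1 fell and 1 did not pass, the same adjusted over the list alone. MT-ND2 rose 3.13-fold (1.65 ± 0.17), MT-ND1 2.34-fold (1.23 ± 0.11), MT-ND3 1.73-fold and MT-ATP6 1.64-fold, and MT-ND6, which is encoded on the other strand, fell (-0.41). Camera gave a Benjamini-Hochberg adjusted p = 0.00124, with adjusted p = 0.492 with an estimated correlation. Mitochondrial genes took 2.83%, 2.97% and 2.96% of counts in artesunate replicates 1 to 3 and 2.10%, 2.38% and 2.03% in the controls. Of 41 nuclear oxidative phosphorylation genes 10 fell, 4 rose and 27 did not pass (8 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.104). SDHA (-0.74 ± 0.06), UQCRC1 (-0.67 ± 0.07) and NDUFV1 (-0.56 ± 0.08) fell. This list was called down in 6 alternatives: library size alone (camera, Benjamini-Hochberg adjusted p = 0.00267), without artesunate replicate 2 (0.00689), log2(FPKM + 1) (0.00776), upper quartile factors (0.0342), no filter (0.0364) and symbol rows alone (0.0394). It had an adjusted p = 0.710 with an estimated correlation.

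Cytosolic ribosomal protein genes rose by small amounts: 61 of 75 rose, 0 fell and 14 did not pass (64 and 0 adjusted over the list alone). RPS12 (1.07 ± 0.15), RPS29 (1.01 ± 0.18), RPL37 (0.87 ± 0.15) and RPL34 (0.86 ± 0.17) led, the list median was 0.53, and it was 0.35 with library size alone. The list passed camera with a Benjamini-Hochberg adjusted p = 2.73e-11, with adjusted p = 0.50 with an estimated correlation. The list's median log2 difference from the controls was 0.21 in artesunate replicate 1 against 0.73 and 0.66 in replicates 2 and 3. More ribosome biogenesis and MYC target genes fell than rose: 15 of 39 fell, 4 rose and 20 did not pass, the same adjusted over the list alone. The list median was -0.19, with MYBBP1A (-1.06 ± 0.11), BOP1 (-1.02 ± 0.09), CAD (-1.01 ± 0.08) and NME1 (-0.93 ± 0.08) falling most. Camera gave a Benjamini-Hochberg adjusted p = 0.0167, with adjusted p = 0.234 with an estimated correlation. MYC was at 109 ± 39.6 against 167 ± 31.6 CPM (-0.61 ± 0.30; edgeR, Benjamini-Hochberg adjusted p = 0.135) and was called by DESeq2 (adjusted p = 0.0304) and in the 3 FPKM fits (-1.05 to -1.07; limma, Benjamini-Hochberg adjusted p = 0.00274 to 0.0107).

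B cell genes fell. Of 30 genes of B cell identity and the B cell receptor 26 fell, 0 rose and 4 did not pass (27 and 0 adjusted over the list alone): VPREB3, TCL1A (-1.99 ± 0.07), the complement receptor gene CR2 (-1.92 ± 0.19) and CD24 (-1.45 ± 0.19) fell most. Of 16 MHC class II genes 13 fell, 2 rose and 1 did not pass (14 and 2 adjusted over the list alone). HLA-DMB (-1.86 ± 0.15), the class II transactivator gene CIITA (-1.58 ± 0.14), HLA-DOA (-0.98 ± 0.08) and HLA-DQB1 (-0.84 ± 0.20) fell, and the regulators RFXANK (0.28) and RFXAP (0.24) rose. Camera passed for both (Benjamini-Hochberg adjusted p = 3.19e-10 and 5.83e-05), with adjusted p = 0.234 and 0.355 with an estimated correlation. Of 22 plasma cell and activated B cell genes 8 rose, 9 fell and 5 did not pass (9 and 10 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.711). FKBP11 (1.33 ± 0.16), SLAMF7 (1.24 ± 0.18), XBP1, a transcription factor gene of secretory cells (1.23 ± 0.15), and SSR4 (1.21 ± 0.11) rose.

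Autophagy and lysosome genes rose. Of 40 genes 29 rose, 5 fell and 6 did not pass (31 and 6 adjusted over the list alone), with LAMP3 9.50-fold higher (3.25 ± 0.41), SQSTM1 8.73-fold, GABARAPL1 5.08-fold (2.35 ± 0.20) and MAP1LC3B 4.18-fold (2.06 ± 0.13). The list passed camera with a Benjamini-Hochberg adjusted p = 5.83e-07, with adjusted p = 0.409 with an estimated correlation.

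The called markers of other cell types had mean levels of 0.0590 to 18.04 CPM. Of the markers with a row in the table, 8 of 15 for T and NK cells and 5 of 16 for myeloid cells were tested. For fibroblast, epithelial and endothelial cells 7 of 15 were tested. The others had too few counts. KLRD1 (0.502 against 0.0590 CPM) rose and CD4 (1.91 against 5.59 CPM) and CD247 (1.72 against 4.53 CPM) fell among 8 tested T and NK cell markers, and 5 did not pass. CD14 (1.76 against 0.595 CPM) rose among 5 myeloid markers, and 4 did not pass. Among 7 fibroblast, epithelial and endothelial markers EPCAM (13.5 against 8.17 CPM) rose, DCN (0.225 against 2.03 CPM), LUM (0.169 against 0.961 CPM), COL1A1 (3.04 against 7.48 CPM) and PECAM1 (9.0 against 18.04 CPM) fell, and 2 did not pass. Counts adjusted over the list alone were the same for the 3 lists, and camera passed for none (Benjamini-Hochberg adjusted p = 0.398, 0.740 and 0.0929). The calls of PECAM1 and CD14 were lost without artesunate replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.0915 and 0.0654), and both were also lost without control replicate 1 and without control replicate 3, and that of PECAM1 without control replicate 2. The call of CD14 was further lost without artesunate replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0552), by limma-voom (0.0533) and on FPKM with no filter (limma, 0.0562), and that of KLRD1 on FPKM with no filter (limma, 0.0691). The log2 fold change of KLRD1 was 3.06 and became 3.80 without control replicate 3.

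**Figure D2:**
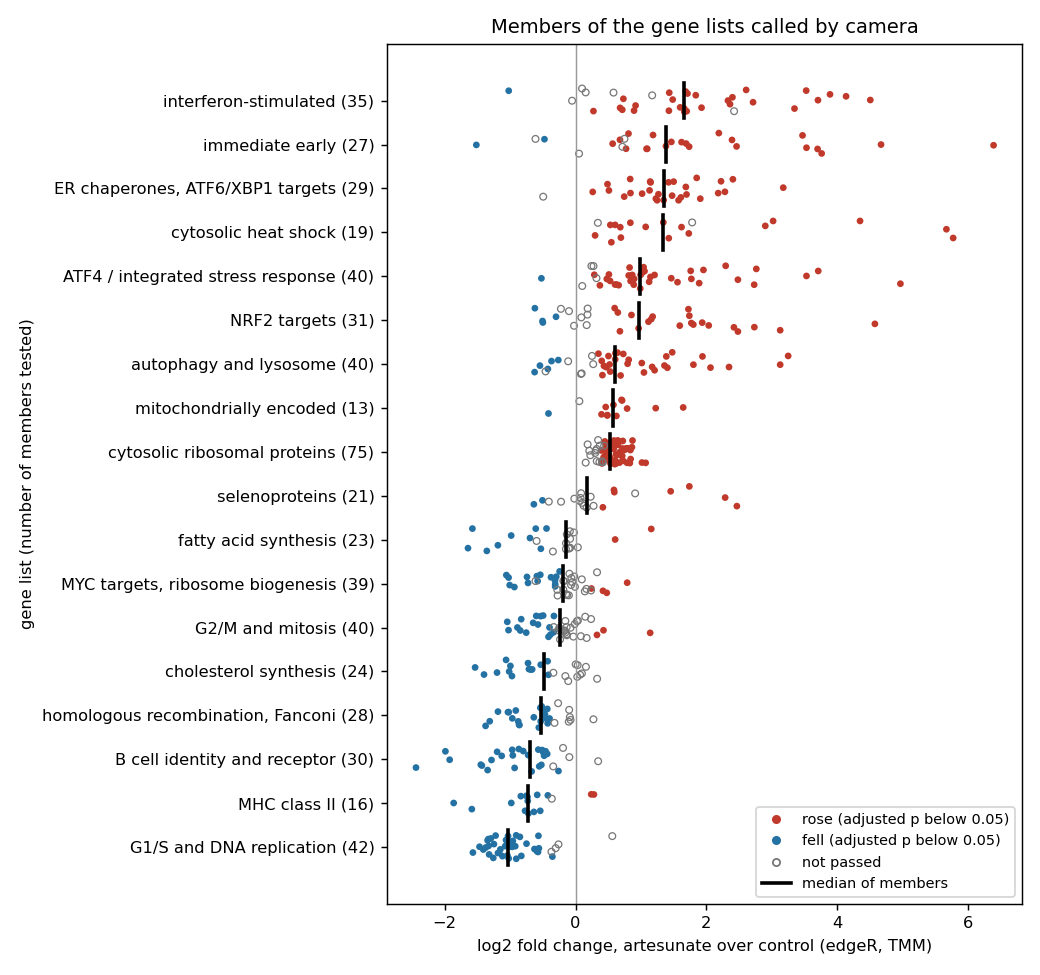
Log2 fold change of artesunate over control (x axis) for every tested member of the 18 gene lists that camera called at its preset correlation, 1 point per gene, with the number of members tested after each name. Red points rose, blue points fell, open points did not pass, and the black bar is the list median: 10 lists lie above 0 and 8 below, from 1.66 for interferon-stimulated genes to -1.03 for DNA replication genes, and the selenoprotein median is -0.05 under the FPKM scaling.

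Of the 32 lists, camera called 18 at its preset correlation of 0.01, 10 up and 8 down, and 0 with an estimated correlation (limma; 23 by fry, which tests each list without comparing it with other genes). Lists called by fry and not by camera were both ferroptosis lists, iron (fry, Benjamini-Hochberg adjusted p = 0.000595), glutathione (0.000986), T and NK cell markers (0.0271) and fibroblast, epithelial and endothelial markers (0.00263). The same preset test called 9 to 15 lists in the 9 other splits of the 6 libraries, in which edgeR called 0 genes. Each of those splits has both treatments in each group. Part of the treatment difference stays between the groups, and part adds to the spread within them. They are not splits without an effect, so these counts cannot rank the camera calls against the counts of genes. The 9 other splits had 34 to 353 genes at an unadjusted p below 0.05, against 9646 in the real split, and limma-voom called at most 1 gene in any of them.

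The libraries separated by group along the first principal component, which held 68.7% of the variance, and artesunate replicate 1 stood apart from replicates 2 and 3 on the second (11.7%), at 46.1 against -22.5 and -14.4. Control replicate 1 lay on the same side (12.1), against -11.4 and -9.95 in control replicates 2 and 3. The median SD of log2 CPM over 16926 genes was 0.196 in the artesunate and 0.122 in the control group.

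**Figure D3:**
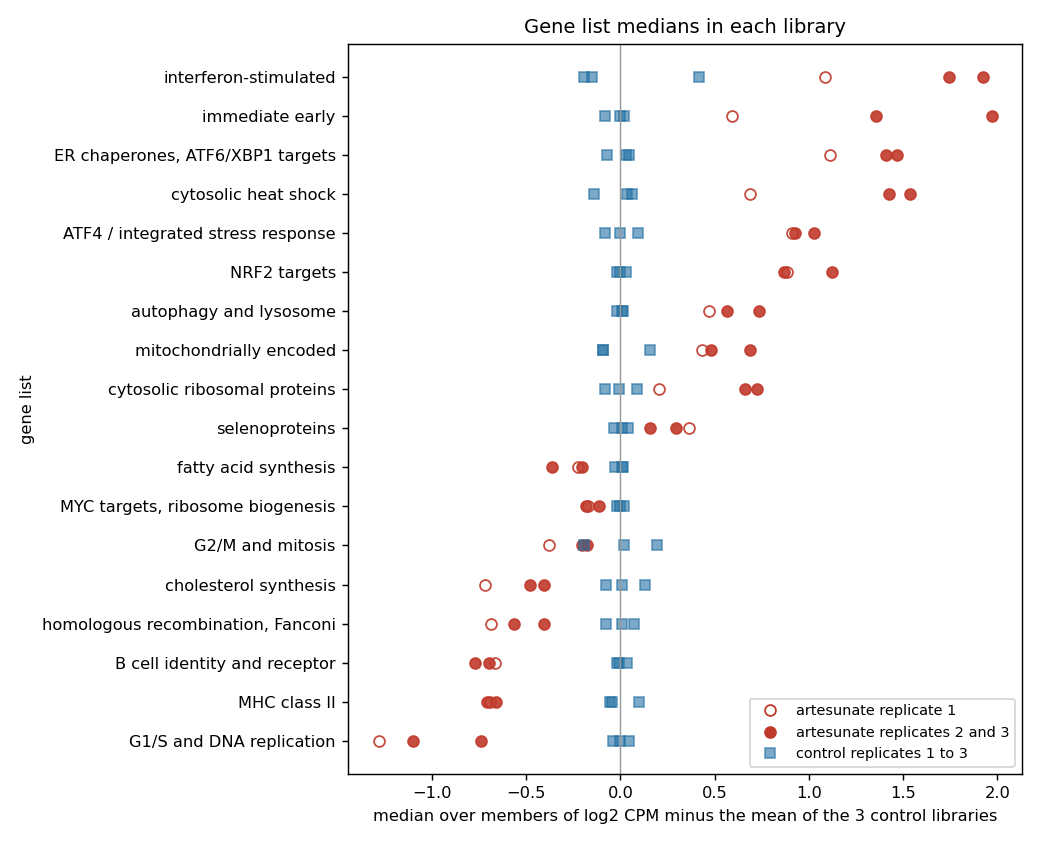
Median over list members of log2 CPM minus the mean of the 3 control libraries (x axis) for the 18 called lists in each library. Open circles are artesunate replicate 1, filled circles artesunate replicates 2 and 3, and squares the controls: replicate 1 lies below the others for heat shock (0.69 against 1.54 and 1.42), and close to them for B cell genes (-0.67 against -0.70 and -0.77).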

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

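The fit without StringTie loci and Ensembl rows and the RLE factors for the gene lists were chosen after the result was seen; the other settings were fixed before the data were examined. Of the 134 called named genes, each refitted in 17 to 20 alternatives, 120 passed in each of those, 14 lost their call somewhere, and 0 turned. Most were picked for large changes, so they do not speak for all calls. Of the 8570 calls, 8432 were shared with limma-voom, 8244 with DESeq2 and 7200 with library size alone. Without control replicate 2 or 3, 6370 and 6611 were shared. Of 7263 present on log2(FPKM + 1), 5842 were called there. Of the called lists 0 turned in direction of the list test, though the median of the selenoprotein list was -0.05 under the FPKM scaling. Of all called genes 31 or 32 changed sign in the FPKM fits. Genes called ran from 7221 to 8693 over the tool, scaling, filter and FPKM settings, and from 6481 (without control replicate 2) to 9384 (without artesunate replicate 1) with a library left out. The share of calls that rose was 50.1% and became 51.4% with DESeq2, 51.7% with RLE factors, 45.2% with upper quartile factors and 34.7% with library size alone. It was 31.4% on log2(FPKM + 1), 31.5% on log2(FPKM + 0.1) and 32.8% on FPKM with no filter. Library size alone moved the median log2 fold change of all genes by -0.17 and log2(FPKM + 1) by -0.17, which lowered that share. DESeq2, RLE and upper quartile factors moved that median by 0.0113, 0.0171 and -0.0532, each in the direction in which the share moved. Whether that was the whole cause was not tested. Genes with at least 2-fold change were 878, 1785 and 880 in those FPKM fits, where the pseudocount shrinks low genes, and 664 with glmTreat, which tests against 2-fold.

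Of the 18 called lists 0 were called with an estimated correlation, and 16 were lost in that setting alone. That correlation was 0.908 for ribosomal protein and 0.884 for heat shock genes. It was -0.0187 for the fatty acid and -0.00824 for the MYC target list, below the preset 0.01. Their unadjusted p still rose (camera, 0.00241 to 0.0285 and 0.00848 to 0.0365), which argues against a higher correlation as the cause for them. The estimated form also takes its degrees of freedom from the 6 libraries, not from the number of genes. That alone raises p for the same statistic. The share of each loss due to this was not measured. The mitotic list was also lost without artesunate replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0644), without control replicate 2 (0.120) and by fry (0.15), and the selenoprotein list with a CPM minimum of 1 (0.0725), the replicate block (0.0504) and symbol rows alone (0.0729). Turned directions were found among results not called. GPX4 was -0.0538 with library size alone and -0.0895, -0.0902 and -0.0895 in the FPKM fits, and NCOA4 -0.0555, -0.0766, -0.0777 and -0.0766. The NF-kB list turned in camera's direction with library size alone (median -0.213), on FPKM (0.00968) and without artesunate replicate 1 (0.0647); its range with a library left out was -0.109 to 0.0647. The BCL2 family list turned with the replicate block (0.0984), on FPKM (-0.201), with symbol rows alone (0.0676), by fry (0.0977) and without control replicate 3 (0.0402), with a range of 0.00975 to 0.161. The hypoxia list turned without artesunate replicate 3 alone (-0.0990), with a range of -0.0990 to 0.131. For these the cause was not tested.

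With the replicate number as a block 9117 genes were called. Deviations of same-numbered libraries correlated at 0.0673 to 0.163, not all above 0.1, so the numbers were not taken to pair the samples; 6 of 6 libraries correlated best with their own number, a hint from the data and not the design. The block ended the calls of CXCL8, DUSP1 and RSAD2 (edgeR, Benjamini-Hochberg adjusted p = 0.0508, 0.0591 and 0.0515). At this depth and spread, simulated data with few changed genes returned 37.3% of 1.5-fold changes. With 8570 genes called in the data the adjustment is less strict than in that simulation, so this share does not carry over. Small changes can still be missed.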

Other observations

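The tests in this part, and the genes named in it, were chosen after the result was seen, except the counts over other splits of the libraries. Gene families defined by a shared symbol stem were also tested: 13 of 458 families were called by camera, and 0 with an estimated correlation (smallest adjusted p = 0.937 with an estimated correlation). Even the metallothionein stem, in which 7 of 7 rose with a median log2 fold change of 7.41, had camera's adjusted p = 0.937 in that form. The estimated form thus had little power over 458 families, and its 0 calls do not weigh against any of them. Not all of the 13 called families are groups outside the lists. The called RPL, RPS, MCM, HSPA, DNAJB and PDIA families share members with the ribosomal, replication, heat shock and chaperone lists. SEC24D and SEC61B of the SEC stem are members of the chaperone list. The SEC stem joins genes of different roles, among them coat, translocon, signal peptidase and SEC14-like genes. In it 17 rose and 3 fell of 27 (camera, Benjamini-Hochberg adjusted p = 0.000467), with SEC24D, a COPII coat gene, at 1.91 ± 0.11 and the translocon gene SEC61A1 at 1.64 ± 0.08 on the log2 scale. In the TMED family 7 rose and 1 fell of 11 (adjusted p = 0.0397), with TMED5 at 1.54 ± 0.09, and in the YIPF family 6 rose and 0 fell of 7 (adjusted p = 0.00552).

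Of 14 proteasome genes with the PSMD stem 10 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 0.00796; adjusted p = 0.937 with an estimated correlation); PSMD12 was at 1.22 ± 0.11 and PSMD14 at 0.92 ± 0.11. The other proteasome stems were not called: PSMC (4 of 7 rose, adjusted p = 0.211), PSMA (6 of 8, 0.0926), PSMB (5 of 10, 0.444) and PSME (1 of 5, 0.880). Coronin genes, which regulate the actin cytoskeleton, fell, 6 of 8 with 0 that rose (adjusted p = 0.0392; adjusted p = 0.937 with an estimated correlation), with CORO1A at -0.90 ± 0.08 and CORO1C at -0.98 ± 0.08.

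Heat shock and immediate early genes were lower in artesunate replicate 1 than in replicates 2 and 3. Control RNA mixed into that library would lower every response alike, and B cell members reached a median fraction of 0.879 (quartiles 0.796 to 1.00, 26 genes) of the response of replicates 2 and 3, against 0.342 (0.148 to 0.439) for 38 heat shock and immediate early genes, which argues against mixing as the whole cause. ATF4 members reached 0.781 (0.648 to 1.19) and 1184 called genes with at least 2-fold change 0.798 (0.624 to 0.956), while DNA replication genes differed more from the controls in replicate 1 (median log2 -1.28 against -0.74 and -1.10). A single scaling factor would move every gene alike, and B cell members differed by a median of 0.17 on the log2 scale (quartiles 0.01 to 0.27) where these 38 genes differed by -0.87 (-1.77 to -0.45), which argues against it. An additive batch effect of like size in both libraries numbered 1 is argued against by a median difference of -0.12 in control replicate 1 (quartiles -0.26 to 0.01). A shared batch effect on how strongly these genes respond to artesunate would not show in the controls, so it stays open. A smaller share of control RNA and a dose, timing or handling difference in that library stay open, and no biological explanation was tested.

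Metallothionein genes rose to the same summed level in each artesunate library, 733 ± 3.15 against 17.2 ± 3.12 CPM over 7 genes (42.6-fold). Sharing of reads between paralogs is argued against by the sum, whose lowest artesunate value was 36.0 times the highest control value, though which member each read belongs to stays open. The gradient of the heat shock genes is argued against by a log2 ratio of 0.00367 between artesunate replicates 2 and 1, where that of heat shock genes was 0.70. A response to metal ions is a candidate explanation: the zinc exporter gene SLC30A1 rose by 3.89 ± 0.18 on the log2 scale (321 ± 71.8 against 21.6 ± 2.12 CPM) and the zinc importer gene SLC39A10 fell (-0.49 ± 0.12; edgeR, Benjamini-Hochberg adjusted p = 0.0102). Another metal importer gene, SLC39A14, rose (0.74 ± 0.07; 108 against 64.9 CPM), so importers did not move together. Metal content was not measured, so this is a hypothesis found and tested on the same data.

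A trend of fold change with transcript length and GC content was weak across genes (Spearman -0.0149 and -0.136 over 13700 genes, 80.9% of those tested), and after it was removed 18 of 18 lists were called in the same direction. On these genes 17 were called before the removal, and for these it argues against that trend as the whole source; the selenoprotein list went from an adjusted p = 0.0714 to 0.0321 (camera, Benjamini-Hochberg), so it gained its call. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 8570 called genes against at most 0 in the others, 2774 with at least 2-fold change against 0, and 18 called lists against 15, and 1 of 10 splits, the real one, reached each of these values. In the others 34 to 353 genes had an unadjusted p below 0.05, limma-voom called at most 1, and preset camera called 9 to 15 lists. Those splits mix treated and control libraries in each group, which widens the spread within groups and keeps part of the treatment difference between them. Their few called genes were therefore likely in advance, and their lists are not a count of false calls.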
